A study of Homo sapiens with 9 samples.

How the data were processed

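RNA from SKOV3 cells transfected with lamin A (control), CDCP1 or PLAGL2 siRNA was measured on 9 Clariom S arrays, 3 per siRNA. Groups and replicate numbers were read from the sample titles, which do not say whether replicates were separate cultures.

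The log2 signals per transcript cluster were made by the authors and deposited after processing that their notes ascribe to Affymetrix Expression Console, whose version was not given. The summarization and normalization methods were not stated in the sources used here. The authors' deposited tables also gave group bi-weight averages on the log2 scale, which are pooled values, and, per the file headers, the standard deviation of the log2 signals in each group. The score in the authors' deposited tables was a signed linear fold of control over knockdown, negative where the knockdown was higher. Each p-value and FDR p-value in those tables was computed by the authors from an analysis of variance, as the file headers state. Deposited folds served only as an alternative to the present fits. Signals were used on the log2 scale as deposited, without further normalization, and no column was left unused.

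The array table held 24351 features. Of these 2903 were control probe sets (among them 612 negative controls, 2197 positive controls and 63 ERCC spike-ins) and were left out of the gene tests, which leaves 21448 transcript clusters, 20389 of them with 1 gene symbol and 1042 with several. A transcript was treated as dim on an array where its signal was at or below the 95th percentile of that array's negative controls. That background was chosen after the files were seen, as were the removal of control probe sets and the use of 1 transcript cluster per symbol, the brightest, in gene lists. A total of 12 transcript clusters reached the array maximum of 19.93 on some array. Gene symbols were the authors', with synonyms matched through a reference annotation that was used for names only, and 17 symbols that a spreadsheet had turned into dates were kept out of the lists, 1 of them past the threshold in some comparison. Coordinates are the authors', with the build not given in the sources used here. Results for some single genes, withheld for evaluation, were left out of the text.

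Differences were estimated with limma 3.58.1 in R 4.3.3, by a linear model with a mean for each of the 3 groups over all 9 arrays, moderated variances (12.7 degrees of freedom) and 3 contrasts: each knockdown against control, and PLAGL2 siRNA against CDCP1 siRNA. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the 21448 transcript clusters of a contrast, and changes passed at an adjusted p under 0.05. The median standard error of a contrast was 0.217 log2 units. Across the arrays, 7147 to 8015 transcript clusters were above background.

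The 25 gene lists, fixed before the data were examined, named 766 entries, of which 717 were measured, and were tested against the other genes of 18616 symbols with camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists of a contrast. Each list was tested again with an estimated correlation and with fry, which tests a list against no change rather than against other genes, and its genes were counted after adjustment over all genes and over the list alone.

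Named genes followed a rule. CDCP1, PLAGL2 and LMNA were named in each contrast. So were the 10 largest increases and 10 largest decreases among changes that passed, with exactly 1 symbol, a mean at or above the median of all transcript clusters in at least 1 of the groups compared, and no overlap between the arrays of the groups. Up to 4 members with the smallest p in each list and 5 genes changed in both knockdowns in each direction completed the rule. From these, list members whose calls held whichever array was left out were preferred. Fold changes are powers of 2 of the difference in group means, and for a gene dim on all arrays of 1 group a lower bound was given against the background level. No fold was given where the lower group's mean was at or below its mean background.

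The shared controls were imitated by 100 simulations without effects and 50 with independent effects, and the fold changes were compared again with different control arrays for each knockdown, a choice made after the data were seen. Every split of the 6 arrays of a contrast into 3 and 3, of which there are 10, was refitted. Alternatives were leaving out each array in turn, quantile normalization, median centring, removal of dim transcript clusters, an intensity trend with robust moderation, fits to only the groups compared, array weights, the replicate number as a block, only transcript clusters with 1 symbol, stricter thresholds and the authors' deposited statistics. Cyclic loess normalization and lists with transcript clusters naming several genes were added after the data were seen.

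The steps were tested on simulated data with the measured variances. With the CDCP1 comparison as template, 100% of 66 planted 4-fold changes, 60.8% of 74 planted 2-fold changes and 5% of 60 planted 1.5-fold changes were recovered, with 7 false calls among 121. With the PLAGL2 comparison as template the shares were 100% of 64, 55.9% of 68 and 8.82% of 68, with 8 false calls among 116. A list shifted by 0.5 log2 units was called in both, and 0 of 22 other lists were. Genes were drawn independently there, so false list calls caused by correlation between genes could not appear. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.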

Results

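Gene expression was measured in the human ovarian cancer line SKOV3 on 9 Clariom S arrays. Cells received 1 of 3 small interfering RNAs (siRNA) by lipofectamine transfection at 50 nM for 48 hours: an siRNA against lamin A that served as the control, an siRNA against CDCP1, or an siRNA against PLAGL2. Each siRNA was represented by 3 arrays. Values were the authors' deposited log2 signals for 21448 transcript clusters, the array's units that each stand for 1 gene or a few overlapping genes.

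The series came from a study of the microRNA miR-654-5p in ovarian cancer, in which CDCP1 and PLAGL2 were followed as targets of a microRNA that restrains tumour growth. CDCP1 is a transmembrane protein phosphorylated by SRC family kinases, and PLAGL2 is a zinc finger transcription factor of the PLAG family. CDCP1 siRNA against control siRNA addressed which transcripts depend on CDCP1, and PLAGL2 siRNA against control siRNA addressed the same for PLAGL2. PLAGL2 siRNA against CDCP1 siRNA addressed how the knockdowns differ, with the control left out of the difference. The control was itself a knockdown of a nuclear envelope protein, so a difference from it holds the effect of a target siRNA and the absence of the lamin A siRNA together.

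Nothing in the labels says that the 3 arrays of a group were separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical. With 3 arrays against 3, the smallest exact p for a single gene is 0.1, so the calls rest on variance shared across genes by limma, at a Benjamini-Hochberg adjusted p under 0.05.

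Array medians lay between 4.19 and 4.24, and between 33.3% and 37.4% of transcript clusters were brighter than the 95th percentile of the negative-control probe sets on the same array, which was 5.50 to 6.01. Correlations between arrays were 0.988 to 0.990 within a group and 0.982 to 0.987 between groups. The leading principal component held 26.3% of the variance and set PLAGL2 siRNA, at 32.7 to 37.2, apart from the other groups, all negative. The next held 18.8% and set control siRNA, at −30.9 to −25.8, apart from CDCP1 siRNA, at 22.3 to 26.2. A total of 12652 transcript clusters were at or below the negative-control level in all groups, which leaves their changes understated.

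The CDCP1 transcript was bright in control cells and almost lost with its own siRNA. On the control arrays it measured 12.49, 12.46 and 12.35 log2 units, with CDCP1 siRNA 6.75, 5.95 and 6.82, and with PLAGL2 siRNA 10.49, 10.69 and 10.76. The mean fell by 5.93 log2 units (standard error 0.23) with CDCP1 siRNA, a 60.8-fold decrease (adjusted p = 4.41e-08). It was also lower with PLAGL2 siRNA than with control siRNA, by a smaller amount. That change was −1.79 (standard error 0.23), 3.45-fold (adjusted p = 0.000657). An effect of the lamin A siRNA on CDCP1 cannot be told apart from it. Between the knockdowns CDCP1 was 4.14 log2 units higher with PLAGL2 siRNA (17.6-fold, adjusted p = 1.24e-06). CDCP1 lies on the minus strand of chromosome 3, from 45082274 to 45146422 in the authors' coordinates, whose genome build was not given in the sources used here.

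**Figure D1:**
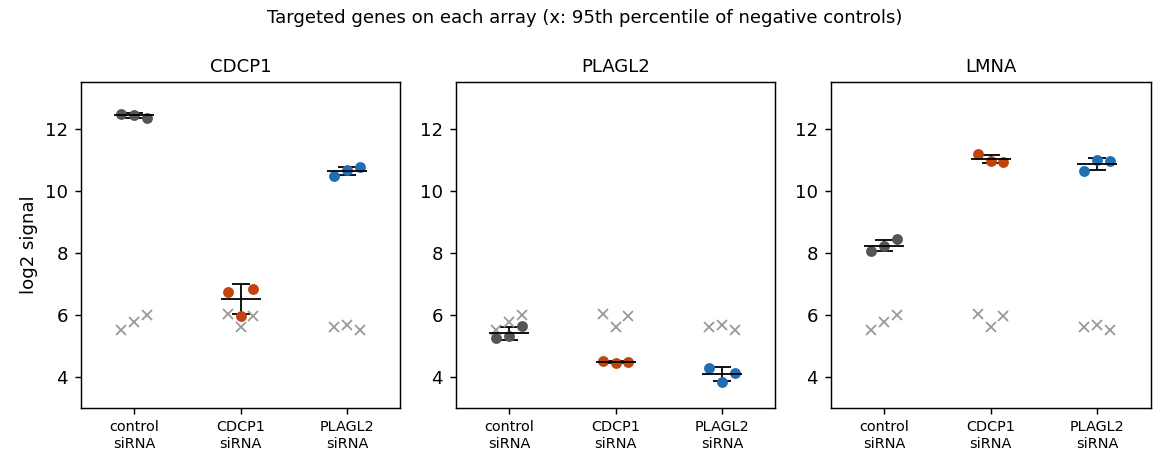
Deposited log2 signal of CDCP1, PLAGL2 and LMNA on each of the 9 arrays, with bars for the mean and SD of each siRNA group and crosses at the 95th percentile of that array's negative controls. CDCP1 averaged 12.43 with control siRNA and 6.50 with CDCP1 siRNA. LMNA averaged 8.23 with control siRNA, which targets it, 11.03 with CDCP1 siRNA and 10.86 with PLAGL2 siRNA. PLAGL2 stayed at or below the crosses throughout.

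The PLAGL2 transcript was dim throughout, so the size of its knockdown could not be read. It measured 5.25, 5.32 and 5.64 on the control arrays, 4.52, 4.44 and 4.48 with CDCP1 siRNA and 4.28, 3.83 and 4.11 with PLAGL2 siRNA, at or below the negative-control level on every array. The mean fell by 1.33 log2 units with PLAGL2 siRNA (standard error 0.19, adjusted p = 0.00123) and by 0.93 with CDCP1 siRNA (standard error 0.19, adjusted p = 0.0215). The difference between the knockdowns was −0.40 (adjusted p = 0.325), so PLAGL2 siRNA did not separate from CDCP1 siRNA on its own target. The decrease with CDCP1 siRNA no longer passed without control replicate 2 (adjusted p = 0.0619) or 3 (0.0923), or without CDCP1 siRNA replicate 1 (0.0590), 2 (0.0847) or 3 (0.0709). PLAGL2 lies on the minus strand of chromosome 20, from 32192503 to 32207791.

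LMNA, the gene for lamin A and the target of the control siRNA, was lower in control cells than in either knockdown. It measured 8.06, 8.21 and 8.43 on the control arrays, 11.17, 10.98 and 10.94 with CDCP1 siRNA and 10.65, 10.98 and 10.95 with PLAGL2 siRNA. Relative to control it was higher by 2.80 log2 units with CDCP1 siRNA (standard error 0.18, 6.95-fold, adjusted p = 7.70e-06) and by 2.63 with PLAGL2 siRNA (standard error 0.18, 6.18-fold, adjusted p = 9.01e-06). The knockdowns differed from each other at LMNA by −0.17 (adjusted p = 0.758). LMNA lies on the plus strand of chromosome 1, from 156082546 to 156140089.

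CDCP1 siRNA lowered more transcripts than it raised. Among the largest decreases were F3, which encodes tissue factor, the actin regulator LIMK1, the ephrin receptor EPHB2 and the sialomucin PODXL. The sterol enzyme MSMO1 fell by a similar amount. The largest increases were in OSTM1, in LMNA, the target of the control siRNA, and in RAB14, a GTPase of membrane traffic. All were higher with PLAGL2 siRNA too. In all, 454 transcript clusters passed, 159 higher and 295 lower (65.0%), and 106 of the higher and 200 of the lower changed at least 2-fold. The count fell whichever of the compared arrays was left out: it was 277, 248 and 262 without control replicate 1, 2 or 3, and 300, 258 and 271 without CDCP1 siRNA replicate 1, 2 or 3.

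F3 went from 15.39 ± 0.19 (mean ± SD) to 11.94 ± 0.16 with CDCP1 siRNA, a 10.9-fold decrease (adjusted p = 7.58e-07). LIMK1 went from 9.54 ± 0.15 to 5.85 ± 0.69 (adjusted p = 2.55e-05), at background on 2 of its 3 CDCP1 siRNA arrays, so no fold is given. MSMO1 went from 13.84 ± 0.38 to 10.87 ± 0.11, 7.82-fold (adjusted p = 1.04e-05). PODXL fell by 2.81 log2 units, 7.03-fold (adjusted p = 3.57e-06). The syntaxin STX3 decreased 8.05-fold, EPHB2 7.97-fold, PPIF 6.10-fold and ANXA4 5.93-fold. OSTM1 rose from 6.94 to 10.03, 8.48-fold (adjusted p = 8.44e-06), and RAB14 rose 6.18-fold (adjusted p = 2.55e-05). Increases followed for TMEM9B (5.34-fold), SCOC (5.33-fold), UBE2V1 (5.21-fold), LAPTM4B (5.20-fold), IDH1 (4.50-fold, adjusted p = 0.000143), the kinase MAPK3 (4.47-fold, adjusted p = 5.96e-05) and LYAR (4.26-fold). All 18 of the largest changes outside the siRNA targets kept their calls whichever array was left out.

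The 25 gene lists fixed before the data were examined were tested as groups against all other genes with camera. The targets of the YAP and TEAD factors moved down most clearly with CDCP1 siRNA: of 20 genes 5 were lower and 0 higher (7 and 0 when adjusted over the list alone), with a median change of −0.50 (adjusted p = 3.72e-09, adjusted p = 0.0128 with an estimated correlation). F3, the growth arrest gene GADD45A (−1.57, adjusted p = 0.000441) and the receptor kinase AXL (−1.24, adjusted p = 0.00103) were among those lower. The integrin, protease and matrix adhesion list of 30 genes held 7 lower and 0 higher (9 and 2 over the list alone), median −0.27 (adjusted p = 1.12e-06, adjusted p = 0.0128 with an estimated correlation). Within it the urokinase gene PLAU changed by −1.31 (adjusted p = 0.00168) while MMP10 went from 7.75 to 5.75, at background on 2 of 3 arrays (adjusted p = 0.00112). The mesenchymal list of 29 genes had 4 lower and 0 higher (7 and 0 over the list alone), median −0.10 (adjusted p = 0.00355, adjusted p = 0.0873 with an estimated correlation).

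Stress and inflammatory groups also fell with CDCP1 siRNA. The ATF4 target list of 30 genes held 3 lower and 0 higher (5 and 0 over the list alone), median −0.32 (adjusted p = 1.98e-07, adjusted p = 0.0229 with an estimated correlation), led by the cystine transporter SLC7A11 (−1.81, adjusted p = 0.000166) and the serine enzyme PSAT1 (−1.45, adjusted p = 0.000659). The hypoxia and glycolysis list of 33 genes held 5 lower and 0 higher (11 and 0 over the list alone), median −0.25 (adjusted p = 9.24e-07, adjusted p = 0.0680 with an estimated correlation). BNIP3L changed by −1.64 (adjusted p = 0.000137), NDRG1 by −1.75 (adjusted p = 0.000276) and VEGFA by −1.08 (adjusted p = 0.00362). The NF-kB inflammatory list of 28 genes held 4 lower and 0 higher (7 and 0 over the list alone), median −0.35 (adjusted p = 1.93e-06, adjusted p = 0.0680 with an estimated correlation). CXCL8 changed by −1.62 (adjusted p = 0.000357), IL1A by −1.33 (adjusted p = 0.000887) and TNFAIP3 by −1.28 (adjusted p = 0.00764). The apoptosis list of 28 genes held 4 lower and 0 higher (9 and 0 over the list alone), median −0.34 (adjusted p = 2.44e-05, adjusted p = 0.0229 with an estimated correlation), and included the TRAIL receptor TNFRSF10B (−1.48, adjusted p = 0.00283).

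Weaker group shifts with CDCP1 siRNA were lost when the correlation between genes was estimated. The list of 25 FOXO targets held down by AKT had 3 lower and 0 higher (the same over the list alone), median −0.07 (adjusted p = 0.0272, adjusted p = 0.102 with an estimated correlation), and lost its call without control replicate 2 (0.0514) or 3 (0.0726) or CDCP1 siRNA replicate 1 (0.113). The MAPK output list of 21 genes had 1 lower and 0 higher (8 and 1 over the list alone), median −0.18 (adjusted p = 0.0165, adjusted p = 0.330 with an estimated correlation), and lost its call without control replicate 1 (0.0917) or CDCP1 siRNA replicate 3 (0.160). The G2/M list of 32 genes had 1 higher and 0 lower (2 and 1 over the list alone), median 0.20 (adjusted p = 0.0204, adjusted p = 0.329 with an estimated correlation), and lost its call without control replicate 3 (0.0815) or CDCP1 siRNA replicate 2 (0.147). The 57 ribosomal protein genes had 2 higher and 0 lower (the same over the list alone), median 0.22 (adjusted p = 7.14e-05, adjusted p = 0.498 with an estimated correlation), and lost their call without control replicate 3 (0.0549). Positive-control probe sets on the same arrays were shifted by a median of 0.0860, less than the ribosomal group.

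Groups tied to the targets themselves, and several others, were not called against the other genes with CDCP1 siRNA. The 26 genes of CDCP1 partners and the SRC pathway had a median of −0.04 with 1 higher and 3 lower (1 and 5 over the list alone, adjusted p = 0.137), although STAT3 rose by 1.61 (adjusted p = 0.00306). The 14 PLAG family targets, 3 of them above background, had a median of −0.01 with 0 higher and 1 lower, over the list alone as well (adjusted p = 0.779), and the 26 WNT genes, 7 above background, −0.01 with 0 higher and 1 lower by either adjustment (adjusted p = 0.573). MYC itself fell by 2.16 (adjusted p = 0.000403) while the 29 MYC targets held 0 changed genes and a median of 0.07 (adjusted p = 0.573). The p53 list of 23 had a median of −0.02, 1 higher and 3 lower (3 and 4 over the list alone, adjusted p = 0.327). The G1/S list of 32 had a median of −0.11 and 1 higher (adjusted p = 0.878), and the epithelial list of 30 a median of 0.09 and 1 lower (adjusted p = 0.573). The 22 lamina and nuclear envelope genes had a median of −0.16 and 1 lower (adjusted p = 0.137). Tested by fry against no change rather than against other genes, the CDCP1 partner list (adjusted p = 0.0165) and the lamina list (adjusted p = 0.0124) were called down.

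Metabolic and immune groups likewise gave no call with CDCP1 siRNA, although the oxidative phosphorylation median was about as large as that of the called G2/M list. The oxidative phosphorylation list of 47 had a median of 0.20 and 1 lower gene, SDHD at −1.08 (adjusted p = 0.0084), with a group adjusted p = 0.137. The fatty acid list of 29 had a median of 0.01 and 0 changed genes (3 higher and 1 lower over the list alone, adjusted p = 0.427). The medians of the endoplasmic reticulum chaperone list of 22 (0.03), the cholesterol list of 24 (0.03) and the interferon list of 37 (0.07) were positive while their means were −0.07, −0.09 and −0.02 and camera pointed down (adjusted p = 0.564, 0.811 and 0.942). Each of these 3 held 1 lower and 0 higher gene, which were 1 lower, 2 lower, and 1 lower with 1 higher over the list alone. The lower interferon gene was IFI6 (−1.28, adjusted p = 0.00539). The 23 leukocyte, endothelial and stromal markers, 1 of them above background, had a median of 0.11 and 0 changed genes (1 lower over the list alone, adjusted p = 0.878).

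PLAGL2 siRNA changed more transcripts than CDCP1 siRNA did, again mostly downward. It lowered the lipid enzyme GPAT3, the cofilin CFL2, transglutaminase TGM2, the cell-cycle kinase CDK2 and the apical protein MAL2. It raised the glucose transporter SLC2A1, the angiogenic factor VEGFA, the secreted hormone STC1 and a set of interferon-stimulated genes. In all, 780 transcript clusters passed, 283 higher and 497 lower (63.7%), and 174 of the higher and 341 of the lower changed at least 2-fold. Without control replicate 1, 2 or 3 the count was 503, 519 and 519, and without PLAGL2 siRNA replicate 2 it was 517.

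GPAT3 went from 10.77 ± 0.05 to 7.17 ± 0.40 with PLAGL2 siRNA, a 12.1-fold decrease (adjusted p = 9.01e-06). CFL2 decreased 11.3-fold (adjusted p = 9.01e-06). TGM2 went from 8.72 ± 0.39 to 5.52 ± 0.28 (adjusted p = 9.36e-06), at background on 2 of 3 PLAGL2 siRNA arrays, and CDK2 from 9.55 ± 0.09 to 6.49 ± 0.20, 8.34-fold (adjusted p = 1.07e-05). CYB5B decreased 9.18-fold, UHMK1 7.36-fold, RAP2C 6.97-fold and HOXB6 6.17-fold. NGDN and CASP2 reached the negative-control level on every PLAGL2 siRNA array, so only a lower bound on their decreases can be given, taking that level as the most the transcript could measure: at least 2.90-fold (adjusted p = 2.10e-05) and at least 3.19-fold (adjusted p = 6.76e-05). SLC2A1 rose from 11.09 ± 0.29 to 13.46 ± 0.08, 5.15-fold (adjusted p = 1.90e-05), and STC1 from 10.08 ± 0.15 to 12.35 ± 0.23, 4.84-fold (adjusted p = 1.96e-05). CCNA1, the meiotic cyclin A, rose 5.71-fold (adjusted p = 5.37e-05). OSTM1 rose 9.08-fold (adjusted p = 9.01e-06), SCOC 5.86-fold, LAPTM4B 5.01-fold, MAPK3 4.87-fold, RAB14 4.87-fold and TMEM9B 4.86-fold. All 19 of the largest changes outside the siRNA targets kept their calls whichever array was left out.

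Interferon-stimulated genes formed the clearest group shift with PLAGL2 siRNA. Of 37 genes 6 were higher and 0 lower (8 and 0 over the list alone), with a median of 0.37 (adjusted p = 1.25e-08, adjusted p = 0.0143 with an estimated correlation). RSAD2 rose by 1.81 (adjusted p = 0.000119), IFIT2 by 1.66 (adjusted p = 0.00186), IFIT1 by 1.59 (adjusted p = 0.00468) and the immunoproteasome subunit PSMB9 by 1.31 (adjusted p = 0.00113). No other list kept its call with an estimated correlation. The hypoxia and glycolysis list of 33 held 7 higher and 0 lower (11 and 2 over the list alone), median 0.23 (adjusted p = 6.04e-06, adjusted p = 0.108 with an estimated correlation). In it VEGFA rose by 1.74 (3.35-fold, adjusted p = 6.76e-05), P4HA1 by 1.30 (adjusted p = 0.00575) and BNIP3 by 1.10 (adjusted p = 0.00399).

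Cell-cycle groups split with PLAGL2 siRNA. The G2/M list of 32 held 6 higher and 0 lower (13 and 2 over the list alone), median 0.39 (adjusted p = 5.53e-06, adjusted p = 0.108 with an estimated correlation), including CCNB2 at 1.18 (adjusted p = 0.00138) and TTK at 1.08 (adjusted p = 0.00998). The G1/S list of 32 held 2 higher and 4 lower (4 and 8 over the list alone), median −0.19 (adjusted p = 0.0256, adjusted p = 0.308 with an estimated correlation). CDC6 changed by −1.06 (adjusted p = 0.00681) and the chromatin reader UHRF1 went from 6.94 to 5.44, at background on 2 of 3 arrays (adjusted p = 0.00362). The G1/S call was lost without control replicate 1 (0.0556) or 2 (0.0620) or PLAGL2 siRNA replicate 1 (0.0548) or 2 (0.103), and also after quantile (0.0628) or cyclic loess (0.0531) normalization or without dim transcript clusters (0.0850). The MYC target and nucleolar list of 29 held 1 higher and 4 lower (1 and 6 over the list alone), median −0.23 (adjusted p = 0.0141, adjusted p = 0.211 with an estimated correlation), and lost its call without control replicate 2 (0.0782). Spermidine synthase SRM fell 2.82-fold (adjusted p = 0.00185), CDK4 fell by 1.46 (adjusted p = 0.00364), NIP7 by 1.03 (adjusted p = 0.00652) and MYC itself by 1.31 (adjusted p = 0.00871).

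The cholesterol list of 24 held 6 lower and 0 higher with PLAGL2 siRNA (7 and 2 over the list alone), median −0.34 (adjusted p = 0.00431, adjusted p = 0.108 with an estimated correlation). HMGCS1 fell by 1.63 (adjusted p = 0.00285) and MSMO1 by 1.30 (adjusted p = 0.00334). The lamina and nuclear envelope list of 22 held 2 lower and 0 higher (3 and 0 over the list alone), median −0.35 (adjusted p = 0.0141, adjusted p = 0.108 with an estimated correlation), and lost its call without control replicate 2 (0.0537). Its lower genes were lamin B1, LMNB1 (−2.13, 4.38-fold, adjusted p = 0.000163), and the nuclear pore gene NUP153 (−1.04, adjusted p = 0.00383). The MAPK output list of 21 held 3 lower and 0 higher (5 and 1 over the list alone), median −0.23 (adjusted p = 0.0256, adjusted p = 0.377 with an estimated correlation), and lost its call without control replicate 1 (0.113) or 2 (0.0537), after quantile (0.0580) or cyclic loess (0.0513) normalization and with fry (0.0883).

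PLAG family targets and WNT genes gave no group call with PLAGL2 siRNA, but only 3 of 14 PLAG targets and 7 of 26 WNT genes were above background, so changes of most members may be understated. The PLAG targets had a median of −0.15 and a mean of 0.02, with 1 higher and 0 lower by either adjustment (adjusted p = 0.878, direction down). The higher gene was BNIP3 (1.10, adjusted p = 0.00399), a reported PLAGL2 target that is also in the hypoxia and FOXO lists. It was also the only PLAG target called over all genes in the other comparisons. The WNT list had a median of −0.01 with 0 higher and 3 lower by either adjustment (adjusted p = 0.525), among them the WNT inhibitor DKK1 at −1.67 (adjusted p = 0.0019). The CDCP1 partner list had a median of −0.04, 2 higher and 3 lower (2 and 6 over the list alone, adjusted p = 0.521), with STAT3 at 1.47 (adjusted p = 0.0038) and integrin beta 1, ITGB1, at −1.58 (adjusted p = 0.000428). The FOXO list had a median of 0.07 with 1 higher and 1 lower (adjusted p = 0.525), and the p53 list −0.05 with 1 higher and 1 lower (adjusted p = 0.336). The apoptosis list had a median of −0.07, 3 higher and 2 lower (3 and 4 over the list alone, adjusted p = 0.878), with TNFSF10, the gene for TRAIL, at 1.19 (adjusted p = 0.00513) and its receptor TNFRSF10B at −1.14 (adjusted p = 0.00953).

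Adhesion and epithelial groups held strong single changes after PLAGL2 siRNA. The epithelial list had a median of −0.03, 1 higher and 3 lower, and was not called against other genes (adjusted p = 0.498) but was called down by fry against no change (adjusted p = 0.0354). In it MAL2 fell by 2.38 (adjusted p = 9.01e-06) and the keratin KRT8 went from 15.45 to 13.85 (adjusted p = 0.000306). The mesenchymal list had a median of 0.24, 1 higher and 0 lower (3 and 0 over the list alone, adjusted p = 0.0677). The integrin, protease and adhesion list had a median of −0.16, 2 higher and 3 lower (2 and 6 over the list alone, adjusted p = 0.291), and the YAP and TEAD list −0.06, 0 higher and 2 lower (2 and 3 over the list alone, adjusted p = 0.521). The thrombospondin THBS1 rose by 1.82 (adjusted p = 0.000119) and ITGA2 by 1.02 (adjusted p = 0.00893) while AXL fell by 2.19 (adjusted p = 1.07e-05) and NT5E by 1.06 (adjusted p = 0.00588). The NF-kB list had a median of −0.19 with 2 lower (adjusted p = 0.0740), 1 of them CXCL1 (−1.93, adjusted p = 0.000238).

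The remaining groups after PLAGL2 siRNA gave no call. The ATF4 list had a median of 0.11 with 1 higher, DDIT4 at 1.32 (adjusted p = 0.00112), and a group adjusted p = 0.0950. The endoplasmic reticulum chaperone list had a median of −0.01 and a mean of −0.01 while camera pointed up (adjusted p = 0.878), and its member HYOU1 fell by 1.89 (adjusted p = 0.000119). The fatty acid list had a median of 0.04 and a mean of −0.15 with 1 higher and 4 lower (1 and 6 over the list alone, adjusted p = 0.376). ACSL1 in it fell by 1.73, at least 1.63-fold (adjusted p = 0.000657). The oxidative phosphorylation list had a median of −0.10 with 2 lower (4 over the list alone, adjusted p = 0.0951), 1 of them ATP5B (−1.20, adjusted p = 0.00131). The ribosomal list had a median of −0.03 with 1 lower (adjusted p = 0.801), and the leukocyte, endothelial and stromal markers 0.01 with 0 changed (adjusted p = 0.801).

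**Figure D2:**
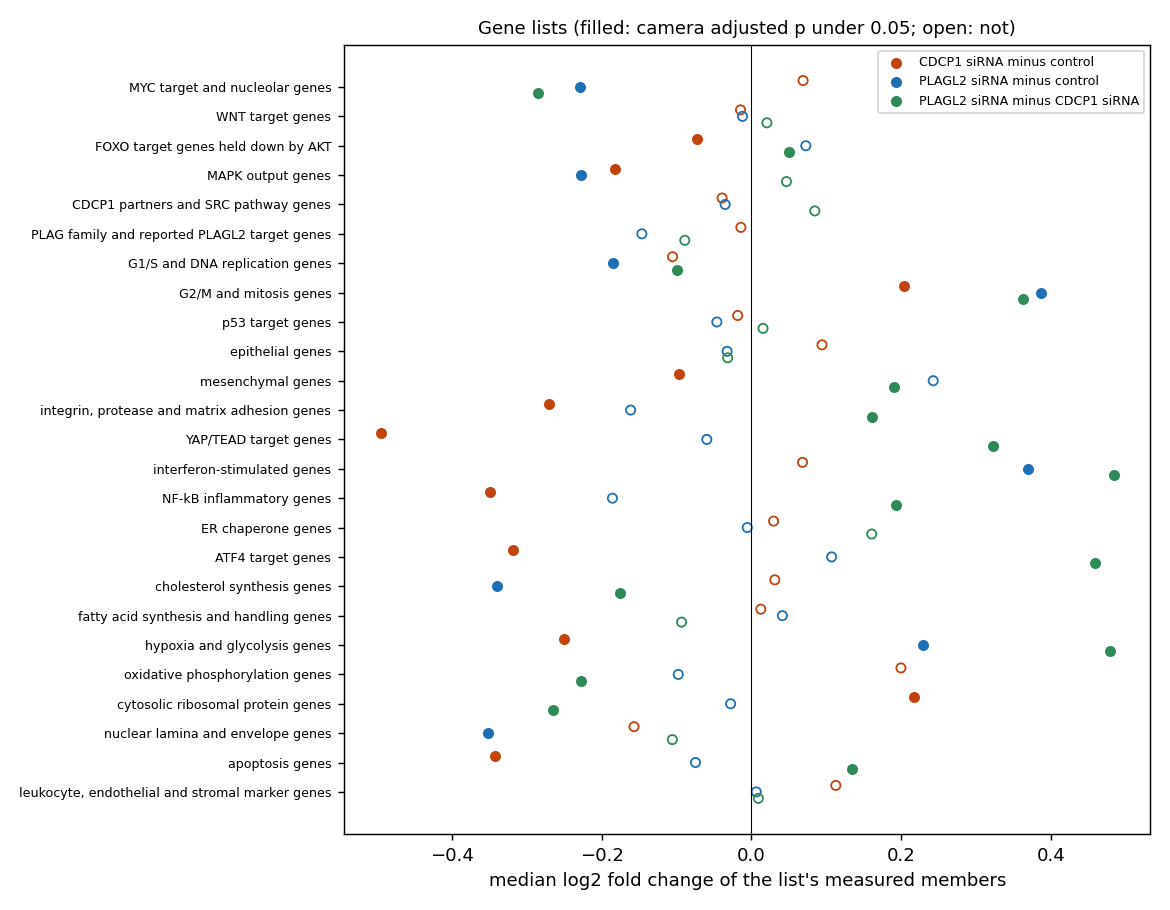
Median log2 fold change of the genes in each of 25 lists for the 3 comparisons, filled where the camera adjusted p was under 0.05. The hypoxia and glycolysis list lay at −0.25 with CDCP1 siRNA and 0.23 with PLAGL2 siRNA relative to control.

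Set against each other, the knockdowns differed at more transcripts than either did from control. F3, VEGFA, STC1 and the matrix metalloprotease MMP2 were higher with PLAGL2 siRNA. GPAT3, TGM2, CDK2 and the lactate transporter SLC16A1 were higher with CDCP1 siRNA. A total of 915 transcript clusters differed, 433 higher and 482 lower with PLAGL2 siRNA (52.7% lower, and 48.7% after cyclic loess normalization, so neither direction dominated), and 277 and 304 of these by at least 2-fold. The count was 607 without CDCP1 siRNA replicate 2 and 604 without PLAGL2 siRNA replicate 2.

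F3 measured 16.08 ± 0.02 with PLAGL2 siRNA and 11.94 ± 0.16 with CDCP1 siRNA, a 17.5-fold difference (adjusted p = 1.62e-07). VEGFA measured 14.22 ± 0.13 against 11.39 ± 0.09, 7.08-fold (adjusted p = 1.68e-06). STC1 was 7.48-fold higher with PLAGL2 siRNA (adjusted p = 3.17e-06), THBS1 6.09-fold, EPHB2 5.62-fold and MMP2 5.49-fold (adjusted p = 0.00022). GPAT3 measured 7.17 against 11.41, 18.9-fold lower with PLAGL2 siRNA (adjusted p = 1.14e-06). UHMK1 was 9.59-fold lower, the semaphorin SEMA6A 8.34-fold, the receptor NMUR2 6.98-fold, the translation factor EIF3F 6.98-fold, CFL2 6.97-fold, SLC16A1 6.92-fold (adjusted p = 8.95e-06), CDK2 6.52-fold and TMEM192 at least 4.62-fold. LIMK1 (9.15 against 5.85), INSIG2 (8.62 against 5.83) and TGM2 (5.52 against 8.55) differed too, but each was at background on 2 of the 3 arrays of its lower group. All 20 of the largest differences outside the siRNA targets kept their calls whichever array was left out.

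The hypoxia and glycolysis, interferon and ATF4 lists separated the knockdowns most clearly, with the smallest adjusted p by camera at either setting of the correlation. Of 33 genes 11 were higher and 0 lower with PLAGL2 siRNA than with CDCP1 siRNA (16 and 0 over the list alone), median 0.48 (adjusted p = 1.63e-14, adjusted p = 0.0198 with an estimated correlation). BNIP3L differed by 2.39 (adjusted p = 5.63e-06), NDRG1 by 2.29 (adjusted p = 2.03e-05), SLC2A1 by 2.16 (adjusted p = 3.20e-05) and BNIP3 by 1.95 (adjusted p = 4.56e-05). The interferon list held 6 higher and 0 lower (13 and 0 over the list alone), median 0.48 (adjusted p = 8.85e-10, adjusted p = 0.0111 with an estimated correlation), with IFIT2 at 1.52 (adjusted p = 0.00292), IFI6 at 1.39 (adjusted p = 0.0018), IFIT1 at 1.36 (adjusted p = 0.0107) and RSAD2 at 1.12 (adjusted p = 0.00338). The ATF4 list held 6 higher and 0 lower (11 and 0 over the list alone), median 0.46 (adjusted p = 2.08e-09, adjusted p = 0.0198 with an estimated correlation). DDIT4 differed by 2.43 (adjusted p = 1.01e-05), SLC7A11 by 2.14 (adjusted p = 2.64e-05), PSAT1 by 1.40 (adjusted p = 0.000456) and NUPR1 by 1.26 (adjusted p = 0.00344).

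**Figure D3:**
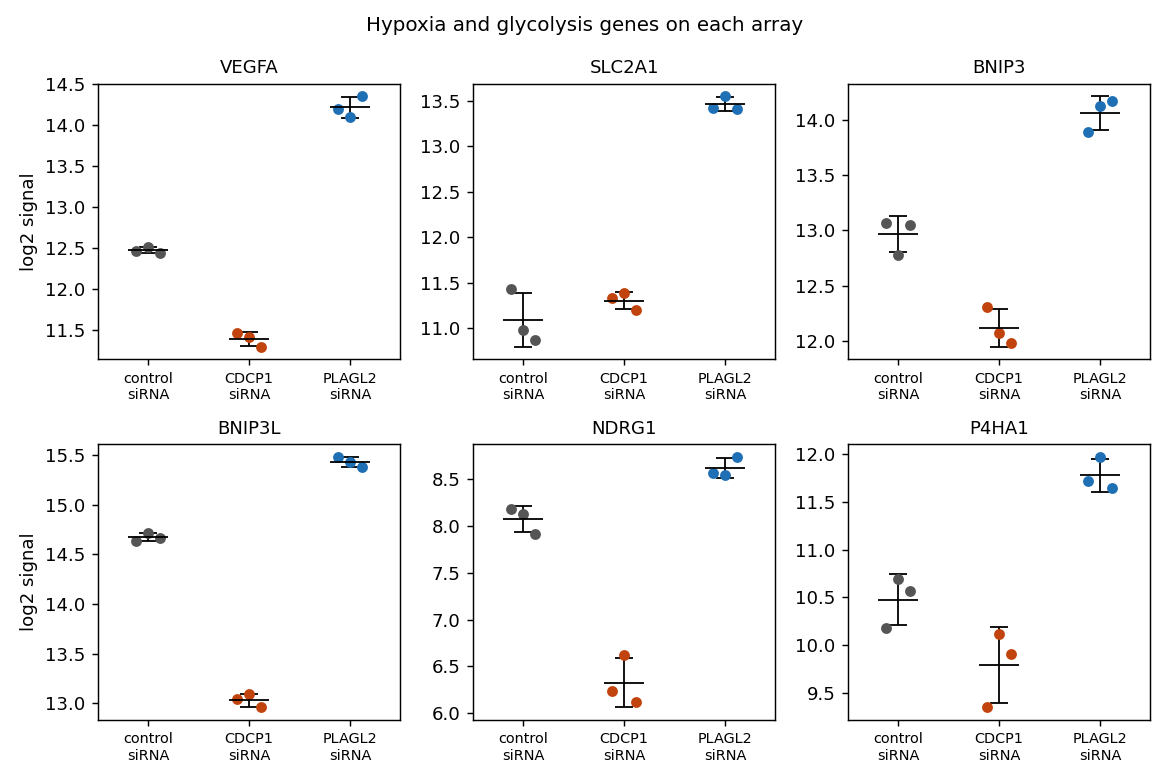
Deposited log2 signal of VEGFA, SLC2A1, BNIP3, BNIP3L, NDRG1 and P4HA1 on each array, with bars for the mean and SD of each siRNA group. VEGFA averaged 11.39 with CDCP1 siRNA and 14.22 with PLAGL2 siRNA.

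Matrix, adhesion and death groups were also higher with PLAGL2 siRNA than with CDCP1 siRNA. The mesenchymal list held 6 higher and 0 lower (7 and 0 over the list alone), median 0.19 (adjusted p = 1.67e-05, adjusted p = 0.0305 with an estimated correlation), with fibronectin FN1 at 1.26 (at least 1.86-fold, adjusted p = 0.00223) and TGFBI at 1.08 (adjusted p = 0.00237). The YAP and TEAD list held 3 higher and 1 lower (4 and 1 over the list alone), median 0.32 (adjusted p = 0.000211, adjusted p = 0.0305 with an estimated correlation), and its lower gene was AXL (−0.94, adjusted p = 0.00406). The integrin, protease and adhesion list held 4 higher and 2 lower (7 and 2 over the list alone), median 0.16 (adjusted p = 0.00422, adjusted p = 0.0423 with an estimated correlation), with MMP10 at 7.84 against 5.75 (adjusted p = 0.000435), the latter at background on 2 of 3 arrays, and ITGA2 at 1.32 (adjusted p = 0.00143). The apoptosis list held 6 higher and 0 lower (8 and 2 over the list alone), median 0.13 (adjusted p = 0.00143, adjusted p = 0.0423 with an estimated correlation). TNFSF10 differed by 1.78 (adjusted p = 0.000255) and PMAIP1 by 1.33 (adjusted p = 0.00169). The NF-kB list held 4 higher and 1 lower (5 and 1 over the list alone), median 0.19 (adjusted p = 0.0120, adjusted p = 0.202 with an estimated correlation), and lost its call without CDCP1 siRNA replicate 3 (0.117). IL6 differed by 1.56 (adjusted p = 0.0022), CXCL8 by 1.20 (adjusted p = 0.00178), IL1A by 1.01 (adjusted p = 0.00357) and CXCL1 by −1.93 (adjusted p = 0.000219). The FOXO list held 3 higher and 0 lower (5 and 0 over the list alone), median 0.05 (adjusted p = 0.0158, adjusted p = 0.0751 with an estimated correlation), and lost its call without CDCP1 siRNA replicate 1 (0.0537) or PLAGL2 siRNA replicate 3 (0.0810).

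Growth and sterol groups were lower with PLAGL2 siRNA than with CDCP1 siRNA, and none of them kept its call with an estimated correlation. The MYC target and nucleolar list held 1 higher and 2 lower (1 and 7 over the list alone), median −0.28 (adjusted p = 0.000874, adjusted p = 0.0705 with an estimated correlation), with SRM at −1.46 (adjusted p = 0.00189) and PHB at −1.04 (adjusted p = 0.0111). The ribosomal list held 0 higher and 4 lower by either adjustment, median −0.27 (adjusted p = 0.000153, adjusted p = 0.429 with an estimated correlation), with RPS12 at −1.34 (adjusted p = 0.00252). The oxidative phosphorylation list held 2 higher and 3 lower (2 and 6 over the list alone), median −0.23 (adjusted p = 0.00143, adjusted p = 0.188 with an estimated correlation), with ATP5B at −1.33 (adjusted p = 0.000581). Positive-control probe sets were shifted by a median of −0.157 between the same arrays, against −0.27 and −0.23 for these lists. The cholesterol list held 1 higher and 4 lower (1 and 5 over the list alone), median −0.17 (adjusted p = 0.0309, adjusted p = 0.0963 with an estimated correlation), and lost its call without CDCP1 siRNA replicate 1 (0.0537) or PLAGL2 siRNA replicate 3 (0.0897), or without dim transcript clusters (0.0514). HMGCS1 differed by −1.72 (adjusted p = 0.00174) and TMEM97 by −1.18 (adjusted p = 0.00341), while MSMO1 differed by 1.67 (adjusted p = 0.00044).

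Cell-cycle groups diverged between the knockdowns. The G2/M list held 2 higher and 1 lower with PLAGL2 siRNA (6 and 1 over the list alone), median 0.36 (adjusted p = 0.00717, adjusted p = 0.202 with an estimated correlation), and lost its call without CDCP1 siRNA replicate 3 (0.0622) or PLAGL2 siRNA replicate 3 (0.0826). HMMR differed by 1.76 (at least 1.74-fold, adjusted p = 0.000244), MKI67 by 0.96 (adjusted p = 0.00613) and KIF2C by −1.75 (adjusted p = 0.000671). The G1/S list held 2 higher and 4 lower (3 and 11 over the list alone), median −0.10 (adjusted p = 0.0346, adjusted p = 0.231 with an estimated correlation). It lost its call without CDCP1 siRNA replicate 3 (0.0667) or PLAGL2 siRNA replicate 1 (0.0668) or 2 (0.127), and also after quantile normalization (0.0503) or without dim transcript clusters (0.0514). CDC6 differed by −1.38 (adjusted p = 0.00097) and UHRF1 measured 5.44 against 6.93 (adjusted p = 0.00317), at background on 2 of 3 PLAGL2 siRNA arrays.

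The other 10 lists were not called between the knockdowns against other genes. Tested by fry against no change, the epithelial (adjusted p = 0.00925), fatty acid (adjusted p = 0.00925) and lamina (adjusted p = 0.00537) lists were called lower with PLAGL2 siRNA. The epithelial list had a median of −0.03, 0 higher and 3 lower (1 and 5 over the list alone, adjusted p = 0.192), with MAL2 at −2.38 (adjusted p = 6.72e-06) and KRT18 at −1.41 (adjusted p = 0.00119). The fatty acid list had a median of −0.09 with 3 lower (5 over the list alone, adjusted p = 0.0878), among them ACSL1 at −2.52 (at least 2.84-fold, adjusted p = 3.20e-05). The lamina list had a median of −0.11 with 4 lower (adjusted p = 0.229), among them LMNB1 at −1.17 (adjusted p = 0.0101). The endoplasmic reticulum chaperone list had a median of 0.16, 1 higher and 2 lower (5 and 4 over the list alone, adjusted p = 0.472), with HYOU1 at −1.34 (adjusted p = 0.00136). The CDCP1 partner list had a median of 0.08, 2 higher and 2 lower (3 and 2 over the list alone, adjusted p = 0.532), with MET at 1.10 (adjusted p = 0.00848) and AKT2 at −1.53 (adjusted p = 0.00172). The WNT list, 6 genes of it above background, had a median of 0.02 and a mean of −0.02 with 1 lower, DKK1 at −1.97 (adjusted p = 0.000486), and the p53 list a median of 0.02 and a mean of −0.01 with 1 lower, CCNG1 at −1.52 (adjusted p = 0.00291). Their group adjusted p were 0.929 and 0.926. The MAPK output list (median 0.05, mean −0.01, 2 lower, adjusted p = 0.944), the PLAG target list (3 genes above background, median −0.09, mean 0.07, 1 higher, 2 higher and 2 lower over the list alone, adjusted p = 0.944) and the leukocyte, endothelial and stromal markers (median 0.01, 0 changed, adjusted p = 0.926) stayed flat.

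The knockdowns shared a set of changes relative to control. OSTM1, SCOC, LAPTM4B and RAB14 were higher with both siRNAs, as was LMNA, the control siRNA's own target. Besides CDCP1, the cyclin-dependent kinase partner CKS1B, the membrane protein EMP1, APBB2 and the stress granule gene G3BP1 fell with both. In all, 75 transcript clusters were higher in both knockdowns, where 2.10 would coincide if the calls were independent, and 70 were lower in both, against 6.84. Another 11 changed in opposite directions, against 7.58. These expectations spread the calls over all 21448 transcript clusters, of which 12652 were dim in all groups. Only 16 of 454 and 27 of 780 calls were dim in both groups compared. The expectations are therefore likely too low, and 11 against 7.58 is not read as an excess. The 145 shared in direction fell to 93 without control replicate 2 and to 89 without control replicate 3.

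CKS1B changed by −2.51 with CDCP1 siRNA (adjusted p = 0.000659) and by −1.76 with PLAGL2 siRNA (adjusted p = 0.0053). EMP1 changed by −1.70 (adjusted p = 0.00657) and −1.68 (adjusted p = 0.00489), and G3BP1 fell 3.03-fold (adjusted p = 0.000472) and 2.92-fold (adjusted p = 0.000422). APBB2 fell at least 4.90-fold (adjusted p = 0.000225) and 2.96-fold (adjusted p = 0.00469).

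Both comparisons used the same 3 control arrays, which by itself makes the fold changes correlate. Across all transcript clusters the fold changes correlated at r = 0.409 (Spearman 0.412), below the mean of 0.50 that shared controls alone gave in simulations without any effect (range 0.489 to 0.513). Genes are not independent replicates, so this correlation describes the profile and carries no p-value. The covariance was 0.0582, against 0.0269 in the same simulations (maximum 0.0279), a difference of 0.0313. Simulations with independent effects in each knockdown gave 0.0270 (maximum 0.0287), with a median of 3 shared increases (maximum 6) and 7 shared decreases (maximum 10). Those effects fell on random transcript clusters, dim ones included, so these shared counts are likely too low as well. When each knockdown was set against different control arrays, 1 for one and the remaining pair for the other, the covariance was 0.0282 on average over the 6 ways (0.0265 to 0.0312) and the correlation 0.159 (0.148 to 0.179). Noise in shared control arrays therefore does not account for that part, but an effect common to all control arrays would remain in it.

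**Figure D4:**
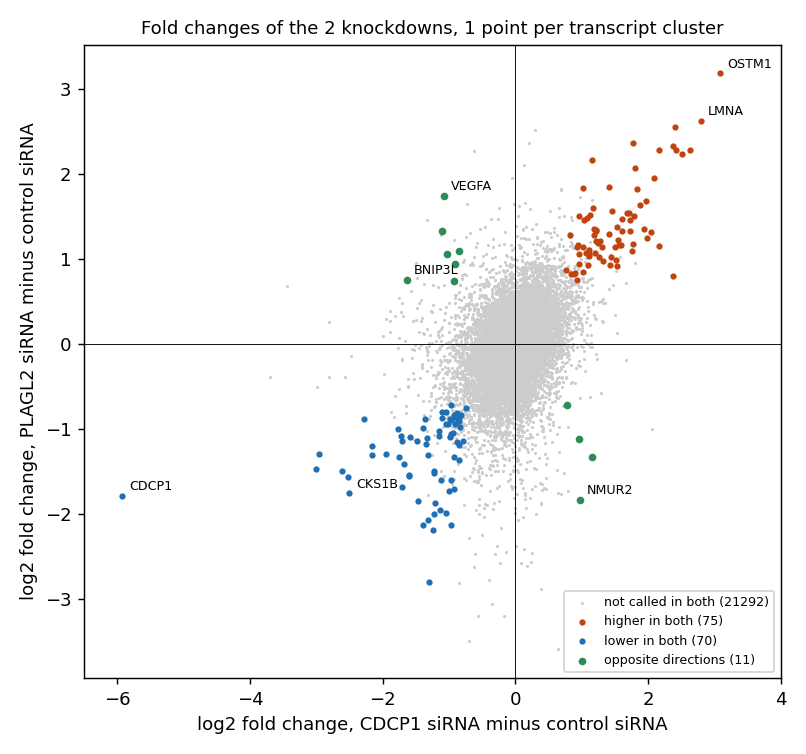
Log2 fold change of each transcript cluster with PLAGL2 siRNA against its log2 fold change with CDCP1 siRNA, both relative to control siRNA, coloured by calls at an adjusted p under 0.05. A total of 75 were higher in both, 70 lower in both and 11 opposite, at a correlation of 0.409 across transcript clusters.

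Genes selected for list membership were less secure than the largest changes. Of 46 list members or shared genes that passed with CDCP1 siRNA under the naming rule, 22 lost the call when some array was left out, as did 24 of 65 with PLAGL2 siRNA and 21 of 71 between the knockdowns. CXCL8, VEGFA and the other list members given values here kept theirs whichever array was left out, but they had been preferred for that reason.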

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

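The tests of gene patterns given here were chosen only after the patterns had been seen, and only the splits of the arrays were planned before the data were examined.

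A few hypoxia-linked genes moved in opposite directions in the knockdowns. VEGFA changed by −1.08 with CDCP1 siRNA and by 1.74 with PLAGL2 siRNA, a difference of 2.82 log2 units, and the autophagy receptor BNIP3L by −1.64 and 0.75, a difference of 2.39. DDIT4, an inhibitor of mTORC1 signalling, changed by −1.10 and 1.32 (difference 2.43), and BNIP3 by −0.85 and 1.10 (difference 1.95). BNIP3 is also in the list of reported PLAGL2 targets. The decrease of BNIP3 with CDCP1 siRNA lost its call without control replicate 1 (adjusted p = 0.107), 2 (0.0509) or 3 (0.103) or CDCP1 siRNA replicate 2 (0.105) or 3 (0.112). The increase of BNIP3L with PLAGL2 siRNA lost its call without control replicate 1 (0.0647), 2 (0.0540) or 3 (0.0593) or PLAGL2 siRNA replicate 1 (0.0635) or 2 (0.0578). The hypoxia and glycolysis list as a whole differed between the knockdowns by a median of 0.479, with 11 of 33 genes higher and 0 lower. Against control 5 of the 33 were lower with CDCP1 siRNA and 7 higher with PLAGL2 siRNA, and neither list call held with an estimated correlation (adjusted p = 0.0680 and 0.108).

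The control arrays take no part in that difference of 0.479. But the list was singled out after it had moved in opposite directions against control, which already implies such a difference. It is therefore no separate test of the lamin A siRNA. Lower oxygen in the PLAGL2 siRNA cultures would raise glycolytic enzymes together with the other members. The 12 glycolytic enzymes differed by a median of 0.489 (standard error 0.134), with 2 called higher, and the other 21 members by 0.435 (standard error 0.284), with 9 called higher. Both standard errors come from the spread across genes, which are not independent, and not from the spread between arrays. These medians do not separate, and lower oxygen is left open. Oxygen readings or culture density records for each well would separate it from a response to either target.

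Beyond the hypoxia genes, a few transcripts changed in opposite directions with the siRNAs, all with clear differences between the knockdowns and most with fragile calls against control. The MYC antagonist MXD1 changed by −0.91 and 0.95 (difference 1.86) and the muscle transcription factor MEF2A by −0.93 and 0.75 (difference 1.67). The neuromedin receptor NMUR2 went the other way, at 0.97 and −1.83 (difference −2.80), as did WDTC1 at 0.96 and −1.12 (difference −2.09) and the chromatin subunit PHF10 at 0.77 and −0.72 (difference −1.50). TMEM189-UBE2V1 changed by 1.16 and −1.32 (difference −2.49), but this readthrough transcript overlaps UBE2V1 and its signal cannot be ascribed to 1 gene.

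The differences between the knockdowns held for all of these whichever array was left out, and the calls against control mostly did not. As the genes were chosen for opposite calls against control, large differences between the knockdowns were already implied and are no separate support. For WDTC1 and NMUR2 the increase with CDCP1 siRNA was lost without any 1 of the control arrays and without CDCP1 siRNA replicate 1 or 2, at adjusted p up to 0.102 for WDTC1 and 0.0863 for NMUR2. For MXD1 the adjusted p rose to 0.170 in the CDCP1 comparison without CDCP1 siRNA replicate 2 and to 0.0889 in the PLAGL2 comparison without PLAGL2 siRNA replicate 2. For MEF2A it rose to 0.0847 without CDCP1 siRNA replicate 2 and to 0.156 without PLAGL2 siRNA replicate 1. For PHF10 it rose to 0.167 without control replicate 3 and to 0.166 without control replicate 2.

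Positive-control probe sets, which target constitutive genes and gave 2197 measurements, changed more often than negative controls. A total of 78 passed with CDCP1 siRNA against control, 67 of them higher, 56 with PLAGL2 siRNA, 26 higher, and 43 between the knockdowns, 9 higher. Their median shifts were 0.0860, −0.0610 and −0.157 log2 units. Negative and spike-in probe sets gave 1, 0 and 1 calls among 706. The ribosomal medians were 0.22, −0.03 and −0.27. The brightest 3% of transcript clusters shifted by medians of −0.0181, −0.0474 and −0.0420, opposite to the positive controls with CDCP1 siRNA and alike in sign in the other comparisons, so a drift with brightness is left open there. The ribosomal median with CDCP1 siRNA was 0.27 after quantile and 0.25 after cyclic loess normalization, and −0.24 after either between the knockdowns. With PLAGL2 siRNA against control its sign was not stable, at 0.04 after quantile normalization.

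Each comparison was refitted for the 10 splits of its 6 arrays into 3 and 3. The labelled split gave 454, 780 and 915 calls, and every other split gave 0, so 1, 1 and 1 of 10 reached the observed counts. A share under 0.05 is not reachable with 10 splits.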

How the results depend on the processing

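The counts of changed transcripts depended more on the number of arrays and the threshold than on normalization. CDCP1 siRNA gave 454, which became 181 at an adjusted p under 0.01 and 248 to 417 with 1 array left out. It was 277, 248 and 262 without control replicate 1, 2 or 3, and 300, 258 and 271 without CDCP1 siRNA replicate 1, 2 or 3. PLAGL2 siRNA gave 780, which became 368 at the stricter threshold and 503 to 758 with 1 array left out, with 503, 519 and 519 without control replicate 1, 2 or 3 and 517 without PLAGL2 siRNA replicate 2. The knockdowns differed at 915, which became 417 and 604 to 858, with 607 without CDCP1 siRNA replicate 2 and 604 without PLAGL2 siRNA replicate 2. Fewer arrays give fewer degrees of freedom, and the part of each fall due to the array itself was not tested.

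Other settings moved these counts by less than 1.5 times. Quantile normalization gave 405, 792 and 943, an intensity trend with robust moderation 587, 931 and 1114, fits to only the groups compared 360, 608 and 675, and array weights 500, 763 and 922. Cyclic loess normalization, chosen after the data were seen, gave 454, 813 and 1009. The share of lower transcripts with CDCP1 siRNA was 65.0% as deposited and 59.0% after quantile normalization. All-transcript medians shifted little, and no called list changed sign with scaling.

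The authors' deposited statistics were stricter. At their FDR under 0.05, 14 transcript clusters passed for CDCP1 siRNA and 27 for PLAGL2 siRNA, 13 and 25 of them also called by limma, while their unadjusted p under 0.05 gave 2112 and 2455. The cause of the gap was not tested. Their folds correlated with the limma values at 0.910 and 0.924 across transcript clusters. CDCP1 passed in both (FDR 0.0480 and 0.0448), as did LMNA (0.0480 and 0.0494). PLAGL2, at −0.93 and −1.33 by limma, was −0.82 and −1.21 in the deposited tables and did not pass (FDR 0.159 and 0.127).

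With 1 array left out, CDCP1 ranged from −6.08 to −5.65 with its own siRNA and from −1.84 to −1.71 with PLAGL2 siRNA. LMNA ranged from 2.71 to 2.89 and from 2.54 to 2.73. PLAGL2 ranged from −1.43 to −1.21 with its own siRNA and from −1.004 to −0.81 with CDCP1 siRNA, where the call was lost without control replicate 2 (adjusted p = 0.0619) or 3 (0.0923) or CDCP1 siRNA replicate 1 (0.0590), 2 (0.0847) or 3 (0.0709). PLAGL2 was at background on every array, which leaves the size of its change unknown.

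Changes shared by the knockdowns numbered 145, and 68 at an adjusted p under 0.01, 4 by the authors' FDR, 632 by their unadjusted p, and 89 to 117 with 1 array left out (93 without control replicate 2 and 89 without replicate 3). The correlation of the fold changes, 0.409, ranged from 0.377 to 0.472 and was 0.451, 0.472 and 0.472 without control replicate 1, 2 or 3. By construction a mean of fewer control arrays carries more shared noise.

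Group tests depended on how the correlation between genes was set. Called lists went from 11, 8 and 15 to 4, 1 and 7 with an estimated correlation, and to 10, 8 and 17 with fry, which tests against no change. With fry the MAPK (adjusted p = 0.0947), G2/M (0.0981) and ribosomal (0.238) lists lost their calls with CDCP1 siRNA and the CDCP1 partner (0.0165) and lamina (0.0124) lists gained one. With PLAGL2 siRNA the MAPK list lost its call (0.0883) and the epithelial list gained one (0.0354). Between the knockdowns the ribosomal list lost its call (0.146) and the epithelial (0.00925), fatty acid (0.00925) and lamina (0.00537) lists gained one. Quantile normalization ended the MAPK (0.0580) and G1/S (0.0628) calls with PLAGL2 siRNA and the G1/S call between the knockdowns (0.0503), and cyclic loess the same calls with PLAGL2 siRNA (0.0513 and 0.0531). Removing dim transcript clusters ended the G1/S calls with PLAGL2 siRNA (0.0850) and between the knockdowns (0.0514) and the cholesterol call between the knockdowns (0.0514). Leaving out 1 array gave 8 to 11, 4 to 10 and 12 to 16, the smallest for PLAGL2 siRNA (4) without control replicate 2. Adding transcript clusters that name several genes, chosen after the data were seen, kept 32 of 34 list calls and ended those of the FOXO list with CDCP1 siRNA (0.0507) and between the knockdowns (0.0669).

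Replicate numbers did not pair the arrays of all groups. Residuals of arrays with the same number correlated at −0.07 to 0.06 and those with different numbers at −0.05 to 0.07, and arrays did not all correlate best with their own number. Between control and CDCP1 siRNA each array did (0.0450 to 0.0589), while all same-number correlations with PLAGL2 siRNA were negative. With a replicate block the counts were 332, 663 and 815, the shared changes 117, and the called lists 11, 8 and 15.

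Of 239 calls for named genes, 213 held in the replicate block fit, 210 with only the groups compared, 230 after quantile normalization and 237 after cyclic loess. The authors' FDR, available for the 148 such calls against control, kept 12 under 0.05 and lost 136. Of 2151 such calls with 1 array left out, 1824 held and 327 were lost, and no call reversed in any setting.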

Other observations

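The gene families here were examined after the gene values had been seen, and the tests of shared changes and of the interferon response were chosen only after those results were known. Metallothionein genes, which bind zinc and copper, separated the knockdowns as a family at the preset correlation only. The 11 genes had a median of −0.54 with CDCP1 siRNA against control (adjusted p = 1.81e-05, adjusted p = 0.678 with an estimated correlation) and 0.28 with PLAGL2 siRNA (adjusted p = 0.0419, adjusted p = 0.506 with an estimated correlation). Between the knockdowns the median was 0.83 with 5 higher (adjusted p = 6.35e-09, adjusted p = 0.296 with an estimated correlation), and MT1X differed by 1.03 (adjusted p = 0.00876) whichever array was left out. The other calls were fragile: without PLAGL2 siRNA replicate 2, MT1G (0.0524), MT1L (0.0553), MT1E (0.0788) and MT1A (0.137) lost theirs and only MT1X of the 5 kept it. Replication-dependent histones had a median of −0.27 with PLAGL2 siRNA against CDCP1 siRNA over 59 genes (adjusted p = 3.66e-05, adjusted p = 0.446 with an estimated correlation). Only 2 of the 59 were called lower: HIST1H1B at −1.18 (adjusted p = 0.00449) and HIST1H2BK at −0.86, which lost its call without CDCP1 siRNA replicate 1 (0.0941) or 2 (0.0808) or PLAGL2 siRNA replicate 1 (0.0915) or 2 (0.0668). Proteasome subunits (45 genes, 4 lower and 1 higher, median −0.24, adjusted p = 0.00404) and tubulins (25 genes, 0 called, median −0.29, adjusted p = 0.00404) leaned the same way, each with adjusted p = 0.296 with an estimated correlation. Families were taken by how gene symbols begin, so PSMC3IP is counted with the proteasome and TUBGCP4 with the tubulins, though neither belongs there. PSMB5 was the largest proteasome difference, at −1.61 (adjusted p = 0.00249), and PSMB9 went the other way at 0.87, a call lost without CDCP1 siRNA replicate 3 (0.0644) or PLAGL2 siRNA replicate 1 (0.0504) or 2 (0.0694).

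Guidance and translation genes gave strong single changes. The semaphorin SEMA6A rose by 2.06 with CDCP1 siRNA (adjusted p = 0.00141) while SEMA7A fell by 1.66 (adjusted p = 0.00909). With PLAGL2 siRNA SEMA6A stood at −1.004 (adjusted p = 0.0686) and SEMA7A at 0.03. The translation initiation subunit EIF3F fell by 2.56 with PLAGL2 siRNA (adjusted p = 3.17e-05) and stood at 0.24 with CDCP1 siRNA (adjusted p = 0.769). The translation repressor EIF4EBP2 fell with both, by 2.16 (adjusted p = 5.96e-05) and by 1.20 (adjusted p = 0.00317). These calls held whichever array was left out.

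LMNA is the direct target of the control siRNA, so its higher level with both other siRNAs is placed with the control. Other genes changed in the same direction by both, such as OSTM1 upward and CKS1B and EMP1 downward, could reflect the lamin A siRNA in the control. They could also reflect a partial loss of CDCP1 in PLAGL2 siRNA cells, although that loss was itself measured only against the lamin A control. An effect carried only by the control should cancel between the knockdowns, and 3 of 75 shared increases and 15 of 70 shared decreases differed there. These genes were picked for moving alike in both comparisons, which by itself favours small differences between the knockdowns. Such differences are also often missed: 60.8% and 55.9% of planted 2-fold changes were recovered in simulations of the comparisons with control. The counts therefore do not show that the shared changes cancel. A shared response to both targets would look the same as a control effect, so the control and the partial loss of CDCP1 are both left open.

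Genes called with CDCP1 siRNA moved with PLAGL2 siRNA by a median share of 0.300 of their change (standard error 0.0415) over 295 lower genes and 0.645 (standard error 0.0549) over 159 higher genes. These standard errors are from the spread across genes, which are not independent, and not between arrays. Simulations with independent effects and shared controls gave 0.0272 (maximum 0.0635) and 0.0307 (maximum 0.0798). Relative to control, CDCP1 itself fell with PLAGL2 siRNA by 0.301 of its fall with CDCP1 siRNA on the log2 scale. On the linear scale the share was 0.722, and how its targets respond to a partial loss is not known. The reverse shares were 0.422 for 283 genes higher with PLAGL2 siRNA (standard error 0.0439) and 0.235 for 497 lower (standard error 0.0279). For lower genes 0.300 is near its reverse of 0.235, while for higher genes 0.645 exceeds its reverse of 0.422. As the response to a partial loss is not known, partial loss of CDCP1 is left open in both directions. A control siRNA without a human target and an siRNA-resistant CDCP1 transcript would bear on the control and on the loss of CDCP1. PLAGL2 was also lower with CDCP1 siRNA than with control, a fragile call at background level. A part of lower PLAGL2 in the shared changes was not tested, and these experiments would not address it.

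Interferon-stimulated genes were higher with PLAGL2 siRNA than with either other siRNA. Against CDCP1 siRNA, without the control arrays, the median difference of the list was 0.484. The list had been called against control with PLAGL2 siRNA only, which already implies such a difference. It is therefore no separate test of the lamin A control. Sensing of the siRNA duplex would be expected to raise interferon and chemokine transcripts, and the median change of IFNB1, IFNL1, CCL5 and CXCL10 with PLAGL2 siRNA was 1.04. CCL5 rose by 1.02 (adjusted p = 0.00372) and CXCL10 from 5.04 to 7.11 (adjusted p = 0.000522), while IFNB1, from 5.03 to 6.09 (adjusted p = 0.0625), and IFNL1 at 0.83 (adjusted p = 0.174) did not pass. The control means of CXCL10 and IFNB1 were below background, so their changes and the median of 1.04 may be understated. CXCL10 reached 6.83 with CDCP1 siRNA too (adjusted p = 0.00224), while CCL5 (−0.62), IFNL1 (−0.29) and IFNB1 (0.18) did not pass there. A response to loss of PLAGL2 could give the same rise, so the median of 1.04 cannot tell it from sensing. Sensing of the duplex is left open, and a PLAGL2 siRNA of another sequence would test it.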
